A study of Rattus norvegicus with 12 samples.

How the data were processed

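The data are QuantSeq 3' mRNA sequencing of uterine tissue from 8-week-old female rats, with 1000 ng of total RNA per library and single-end reads of 75 bp. The labels title every sample Endometrium, while the design text says that uterine tissues were harvested, so it is open how much muscle layer the samples hold. The 12 libraries form 4 groups of 3. Normal tissue was uninjured. AS tissue came from horns whose lining was scraped with a bent needle, the series' model of intrauterine adhesion. EEP tissue received a bioprinted endometrial patch carrying cells 2 days after AS induction, and CP tissue received a control patch printed without cells. The labels number the replicates within each group and do not say that a number marks one animal. The design text says that the opposite horn served as an internal control or received the control patch, so horns of one animal could stand in different groups. Shared animals would call for pairing, but the labels do not link samples to animals, so the groups were treated as independent. The replicate number served as a block in an alternative. With group means removed, same-numbered samples of 2 groups correlated at -0.103 to 0.39 over 18 pairs. AS 1 with EEP 1 was highest, and in 9 of the 18 pairs the own number correlated best. Each pair had 3 numbers to choose from, so chance alone gives the own number in 1 of 3 pairs. The count does not settle whether a number marks one animal. The p-values measure the spread between these samples, which the labels do not say are separate animals.

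The labels name Bowtie2 for alignment, bedtools for quantification and edgeR for differential expression, with no versions. One table holds 34034 genes. Its raw counts per gene were deposited by the authors and are whole numbers. The same table holds the authors' log2 values, which are log2(TMM-scaled CPM + 1). Recomputing them from the counts gave differences of at most 0.0335. The authors also deposited a fold ratio of group averages per comparison, and a p-value and q-value per comparison without naming the test. Gene coordinates are on mRatBN7.2 per the authors' information sheet, whereas the processing notes name mm10, a mouse build. The gene symbols and sequence names in the table are those of rat. Chromosome names were assigned through gene symbols shared with a RefSeq table of a later rat assembly. Of the table's gene identifiers, 31680 matched that table.

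All comparisons here start from the raw counts. Total counts ranged from 4866790 to 8938227 per library, and 37 mitochondrial genes took 18.9% to 82.5% of them, which left 1202525 to 5832552 counts for nuclear genes. A count of 3 in a library corresponds to 0.177 to 0.867 CPM. Counts were scaled by TMM and genes were filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, which kept 13909 genes. The biological coefficient of variation was 59.2%. All 12 libraries entered a single quasi-likelihood fit (glmQLFit), and each pair of groups was compared with glmQLFTest. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels per gene are TMM-scaled CPM, counts scaled to library size, given as mean ± SD over n = 3 libraries, and fold changes are log2 values with the standard error of the fit.

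A total of 31 gene lists for the tissue, the injury and other cell types were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. An adjusted p with an estimated correlation is given beside each list that passed. A list is said to rise or fall where camera passed with the preset value. Passing members are counted over all genes tested and, separately, adjusted over the list alone. A fold against a group with 0 counts is a lower bound computed with 3 counts over that group. Where that group held 1 to 3 counts, a pooled ratio with a 95% counting interval is given. Shares of counts in single libraries have 95% Wilson intervals. Intervals and floors cover counting error only. The mitochondrial share was compared between groups by a two-sided exact permutation test, for which 3 libraries against 3 allow no p below 0.1.

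The groups, comparisons, tests, thresholds, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, for 4 comparisons, up to 8 called genes per direction and up to 4 members of each list with the smallest p-values. Where no gene was called, the 5 genes with the smallest p-values were given as not passing. The fixed alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, a stricter filter (5 CPM in 3 libraries), a fit of 2 groups alone, other thresholds, the replicate number as a block, and leaving out each replicate in turn. With a replicate left out, gene calls and lists were redone only for the comparisons that include its group. Alternatives added after seeing the data were removal of the mitochondrial genes, the mitochondrial share as a covariate, and leaving out the AS 1 and EEP 1 libraries together. The procedure was tested on simulated data with the spread of these libraries. The changed genes were drawn from those with a mean of at least 5 CPM, so the recovery of lower genes was not measured. The procedure recovered 34% to 39% of genes changed 4-fold and 90% to 94% of genes changed 16-fold, and called 2 to 11 unchanged genes per comparison. Both lists shifted in the simulation were called and 0 of the other 29 were. The simulated genes were drawn independently, so this does not show how often lists pass when their members move together. In the data, other splits of the AS and normal libraries passed up to 11 lists.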

Results

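Uterine tissue of rats was profiled by 3' mRNA sequencing in 4 groups of 3 libraries each: normal, AS, CP and EEP. AS is the scraping injury with no patch, CP the injury followed by a patch without cells, and EEP the injury followed by a patch with cells. Total counts were 7615145, 7405905 and 6592701 in normal 1, 2 and 3, and 8938227, 7933043 and 6131520 in AS 1, 2 and 3. They were 8077591, 6151017 and 5406379 in CP 1, 2 and 3, and 7195269, 4866790 and 5080068 in EEP 1, 2 and 3. Between 14250 and 18212 genes were detected per library.

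Transcripts of the mitochondrial genome took a large and uneven part of the counts. Their share was 50.2% ± 6.18 (SD, n = 3) in normal tissue, 71.1% ± 3.55 in AS, 71.3% ± 9.76 in CP and 49.6% ± 28.9 in EEP. The EEP libraries differed most among themselves, with 18.9% in EEP 1, 53.6% in EEP 2 and 76.3% in EEP 3, and each library's 95% Wilson interval was at most 0.0886 percentage points wide. All 3 AS libraries and all 3 CP libraries lay above the 3 normal libraries. Each of these differences had an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give, and an adjusted p of 0.3 over the 6 comparisons. Over all tested genes, EEP 1 had a median correlation of 0.883 with the normal libraries, against 0.823 for EEP 2 and 0.752 for EEP 3. The values were 0.799, 0.864 and 0.858 for AS 1, 2 and 3 and 0.765, 0.843 and 0.812 for CP 1, 2 and 3.

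**Figure D1:**
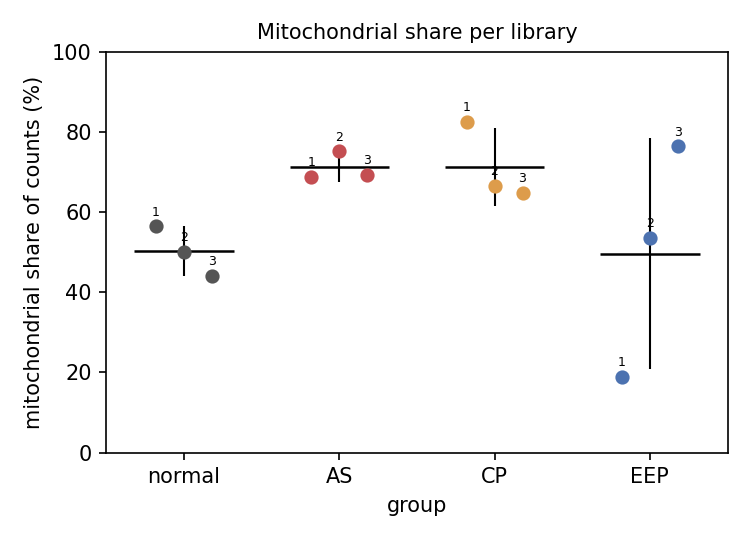
Share of counts from mitochondrial genes (percent, y axis) in each library by group (x axis); points are libraries with their replicate number, horizontal lines are group means and vertical bars the SD of 3 libraries. The EEP libraries run from 18.9% to 76.3%, and the AS and CP libraries lie above the normal libraries.

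AS tissue was compared with normal tissue to see what the scraping injury changes in the uterus. Transcripts of Fam111a, a serine protease that acts in DNA replication and in the restriction of viruses, were nearly lost, at 2.27 ± 1.05 CPM in AS against 80.1 ± 23.4 CPM in normal tissue (SD, n = 3). Genes of the interferon response, markers of macrophages and monocytes, and erythrocyte genes rose as lists, with median log2 fold changes of 1.02, 0.85 and 2.30 (adjusted p = 0.465, 0.491 and 0.465 with an estimated correlation). Lists of matrix proteases and of endometrial stroma fell, with medians of -0.55 and -0.23 (adjusted p = 0.423 and 0.465 with an estimated correlation). In camera these calls thus hold with the preset correlation and not with the estimated one.

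Fam111a (Entrez 499322, chromosome 1, 209640865 to 209656551 on mRatBN7.2) was the single gene called of 13909 tested with edgeR's quasi-likelihood test. Its log2 fold change was -5.14 (SE 0.566, adjusted p = 0.00109), from 36 counts in the 3 AS libraries and 2408 in the 3 normal libraries. It was lower in each AS library than in each normal one, a separation that chance gives for 10% of genes with 3 libraries against 3. Over its alternatives the adjusted p ran from 1.49e-19 to 0.0207. At an unadjusted p under 0.05 there were 371 higher and 401 lower genes, 772 in all, where chance alone gives 695.4, and DESeq2 called 32 genes. Without normal 2, 6 genes were called, and without AS 1, 2 genes.

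Of 22 measured interferon-response genes, 20 were higher in AS and 2 lower (camera adjusted p = 4.56e-09, and adjusted p = 0.465 with an estimated correlation). The members with the smallest p-values were Irf7, the regulator of the type I interferon response, at 54.7 ± 32.8 against 12.01 ± 4.72 CPM, Oas1a and Oas2, which sense viral RNA, and Usp18, which removes ISG15 from proteins. Their log2 fold changes were 2.19, 1.85, 1.82 and 1.80, and none passed over all genes tested, with edgeR or DESeq2, or adjusted over the list alone. Without AS 1 the value of Irf7 was 1.59. Macrophage and monocyte markers were higher for 17 of 20 members (camera adjusted p = 1.99e-04, and adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone, 4 passed, against 0 over all genes tested with edgeR and with DESeq2: Aif1, a calcium-binding protein of macrophages (log2 fold change 1.55), the receptor adaptors Fcer1g (1.75) and Tyrobp (2.11), and the lysozyme Lyz2 (2.55). Without AS 1 the values of Fcer1g, Tyrobp and Lyz2 were 1.03, 0.83 and 0.23. The list still passed at an adjusted p of at most 0.0275 with any single AS or normal library left out. The rise was not shared by all AS libraries. A list score is the mean log2 CPM of the members relative to the mean of all 12 libraries. It was 0.706, 0.539 and -0.473 in AS 1, 2 and 3, against -0.296, -0.526 and -0.0616 in normal 1, 2 and 3. The interferon score was 0.50, 0.51 and -0.227 in AS 1, 2 and 3, and -0.346 in normal 3, the highest normal library. The mitochondrial share was higher in AS than in normal tissue beside both lists, and with the share as a covariate their adjusted p-values were 9.68e-05 and 8.6e-04. Over all alternatives the ranges were 1.81e-11 to 0.465 and 8.37e-08 to 0.491, the highest values being those with an estimated correlation.

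The erythrocyte list was higher for all 7 measured members (camera adjusted p = 4.24e-05, and adjusted p = 0.465 with an estimated correlation). The hemoglobin genes Hba-a1, Hba-a2, Hba-a3 and Hbb-bs passed when adjusted over the list alone, 4 against 0 over all genes tested with edgeR, and DESeq2 called Hba-a3 over all genes. Most of this came from 1 library: Hba-a1 stood at 1830 CPM in AS 1 and at 120 and 242 CPM in AS 2 and AS 3, and without AS 1 the list's adjusted p was 0.277 (range over alternatives 7.36e-10 to 0.465). Log2 fold changes of Hba-a1, Hba-a2, Hba-a3 and Hbb-bs were 2.30, 2.70, 3.65 and 2.53 with AS 1 and 0.26, 0.39, 0.69 and 0.95 without it. MHC class II genes were higher for 10 of 12 members (median 0.67, camera adjusted p = 0.0219, and adjusted p = 0.491 with an estimated correlation). That list did not pass without normal 2 (adjusted p = 0.12), AS 1 (0.418) or AS 2 (0.0602), in a range of 2.59e-05 to 0.491 over its alternatives. RT1-DMa, a peptide-loading chaperone chain, and RT1-DOb, a chain of its modulator, passed adjusted over the list alone, 2 against 0 over all genes tested with edgeR. DESeq2 did not call RT1-DMa and gave no adjusted p for RT1-DOb. The chains of one class II molecule had log2 fold changes of opposite sign, 1.30 for RT1-Ba and -1.45 for RT1-Bb. Neither passed, and their difference was not tested. Without AS 1 the values were 1.07 for RT1-DMa, from 1.89, and 0.71 for RT1-Ba. RT1-DOb was at least 30.1-fold higher with all libraries, at least 14.6-fold without AS 1 and at least 43.7-fold without AS 3.

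Estrogen-induced genes of the uterus rose as a list, 13 of 18 members being higher (median 0.45, camera adjusted p = 0.0239, and adjusted p = 0.491 with an estimated correlation). The list did not pass without normal 1 (adjusted p = 0.102), normal 2 (0.182) or AS 1 (0.338), in a range of 0.00112 to 0.491 over its alternatives. The luminal epithelium score moved with the estrogen score across the 12 libraries (r = 0.788) and stood at 1.62 in AS 1 against -1.73 and -0.64 in AS 2 and AS 3. Greb1, a cofactor of the estrogen receptor (log2 fold change 1.37), the transcription factor gene Fos (1.64) and S100g, the calcium-binding protein calbindin-D9k (3.87), passed adjusted over the list alone, 3 against 0 over all genes tested with edgeR and with DESeq2. S100g stood at 2240 CPM in AS 1 and at 54.5 and 55.3 CPM in AS 2 and AS 3, and without AS 1 its log2 fold change was 0.02. Matrix proteases and their inhibitors were lower for 13 of 18 members (camera adjusted p = 0.0224, and adjusted p = 0.423 with an estimated correlation). They did not pass without normal 3 (0.0601), AS 2 (0.0561) or AS 3 (0.0673), in a range of 0.012 to 0.423. Plau, the urokinase plasminogen activator, was at 13.3 ± 0.899 CPM in AS against 41.7 ± 23.5 CPM, and was the 1 member to pass adjusted over the list alone, against 0 over all genes tested with edgeR and with DESeq2. Mmp2, a gelatinase, had a log2 fold change of -0.69, and Mmp7, the epithelial protease matrilysin, one of 2.08 that rested on AS 1, being -0.10 without it and 3.15 without normal 3. Stromal genes were lower for 14 of 18 members (camera adjusted p = 0.046, and adjusted p = 0.465 with an estimated correlation), with log2 fold changes of -2.32 for Thy1, a fibroblast surface protein, -0.99 for Pdgfra, a receptor of stromal cells, and -0.92 for Dcn, the proteoglycan decorin. Without normal 2 or AS 1 the stromal list did not pass (0.23 and 0.377, in a range of 0.0207 to 0.465). None of the stromal genes passed over all genes tested, with edgeR or DESeq2, or adjusted over the list alone.

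Collagen and fibrotic matrix genes showed no shared direction after injury (12 of 22 lower, median -0.07, mean 0.02, camera adjusted p = 0.988). The smooth-muscle list had a median of 0.30 (adjusted p = 0.0618), with desmin (Des, log2 fold change 1.48, and 0.88 without AS 1) passing adjusted over the list alone, 1 against 0 over all genes tested with edgeR and with DESeq2. In 3 more lists that did not pass, 1 member each passed adjusted over the list alone, against 0 over all genes tested with edgeR, and DESeq2 called the first of them, Tgfb2, over all genes. These were Tgfb2, a TGF-beta ligand (log2 fold change -2.16, and -1.54 without normal 1, list adjusted p = 0.363), the mesothelial membrane protein gene Gpm6a (-4.06, and -3.36 without normal 2, with 4 counts in AS of which 3 lay in AS 3, list adjusted p = 0.529), and the epithelial keratin gene Krt13, whose 36 counts all came from AS 1 with 0 in normal tissue (list adjusted p = 0.354). Tgfb2 stood at 466 and 285 CPM in normal 1 and normal 3. In normal 2 it was at 68 CPM, below AS 2 and AS 3 at 76.7 and 78.5 CPM. Wnt pathway genes had a median of -0.48 (adjusted p = 0.126), with log2 fold changes of -1.92 for Sfrp1, a secreted Wnt antagonist (-2.61 without AS 2), and -3.38 for Lgr5, a receptor on progenitor cells (-4.08 without AS 3). Lgr5 stood at 23.9 and 20.9 CPM in normal 1 and normal 3 but at 3.5 CPM in normal 2, against 2.77 CPM in AS 3. In the progesterone and decidual list (adjusted p = 0.139) Igfbp1, a decidual marker, had a log2 fold change of -5.48, with 200 and 149 CPM in normal 1 and normal 3 against 3.80 CPM in normal 2. Its value was -4.86 without normal 1 and -6.52 without AS 3. Luminal epithelium (median 0.28, mean 0.45, test direction down, adjusted p = 0.988), uterine gland (0.988), endothelium (0.262) and cell cycle genes (0.302) did not pass.

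EEP tissue was compared with AS tissue to see what a patch with cells changes in the injured uterus. Spink5, which encodes a protease inhibitor of stratified epithelia, was at 36.5 ± 6.17 CPM in EEP and at 0.0659 ± 0.114 CPM in AS (SD, n = 3). Fam111a was at 67.5 ± 34.5 CPM in EEP against 2.27 ± 1.05 CPM in AS. Marker genes of stratified epithelium, 4 keratins and the suprabasin gene Sbsn, rose as a list, with a median log2 fold change of 3.84, and contractile genes of smooth muscle fell with a median of -1.09 (adjusted p = 0.0932 and 0.0548 with an estimated correlation). Collagen and fibrotic matrix genes fell with a median of -0.46 (adjusted p = 0.90 with an estimated correlation). Both falls took the group mean below that of normal tissue. The smooth-muscle score was 0.264 ± 0.12 in normal tissue, 0.519 ± 0.227 in AS and -0.655 ± 0.307 in EEP. For collagen and fibrotic matrix the scores were 0.278 ± 0.144, 0.205 ± 0.177 and -0.309 ± 0.481. These lists were not tested between EEP and normal tissue.

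**Figure D2:**
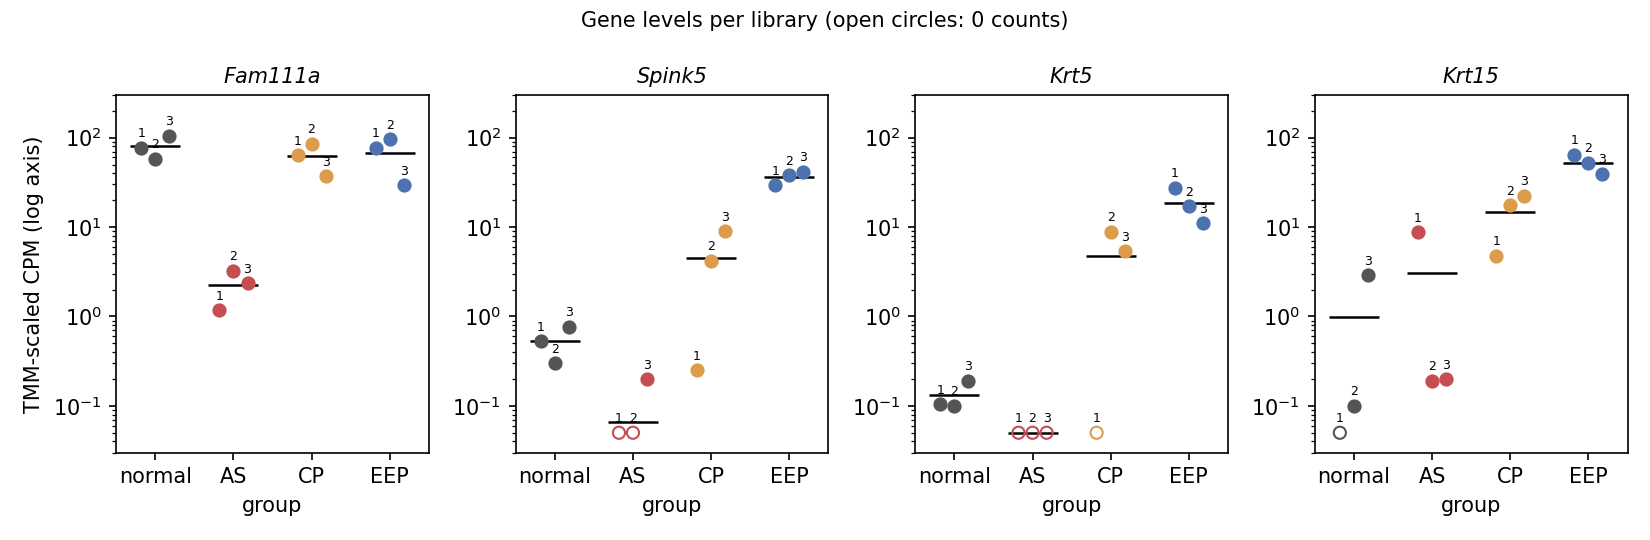
TMM-scaled CPM (log y axis) of Fam111a, Spink5, Krt5 and Krt15 in each library by group (x axis); points are libraries with their replicate number, lines are group means, and open circles and a line at the bottom stand for 0 counts. Fam111a is low in the 3 AS libraries, and the 3 EEP libraries lie above all others for Spink5, Krt5 and Krt15.

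Spink5 (Entrez 361319, chromosome 18, 36264452 to 36333143 on mRatBN7.2) and Fam111a were the 2 genes called, both higher, with edgeR's quasi-likelihood test. Spink5 had 899 counts in EEP and 1 count in AS, a pooled ratio of 540 (95% counting interval 96.7 to 21400, adjusted p = 0.00529). It held most of its counts in EEP and so passed the low-count filter largely through that group. The direction of Spink5 was thus partly set by the filter. Fam111a was 29.8-fold higher (SE of the log2 value 0.561, adjusted p = 0.00189). Each was higher in all 3 EEP libraries than in all 3 AS libraries. At an unadjusted p under 0.05 there were 1410 genes, against 695.4 by chance, and DESeq2 called 140, Fam111a among them but not Spink5, for which it gave no adjusted p. Without AS 3, which held the 1 count, Spink5 was at least 124-fold higher. Without AS 2 its adjusted p was 0.0745, and with the 2 groups fitted alone that of Fam111a was 0.0676, the ranges over the alternatives that gave a value being 1.66e-15 to 0.0745 and 4.01e-17 to 0.0676. Without EEP 1, 19 genes were called.

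Of the stratified-epithelium list, 5 of 16 genes could be tested and all 5 were higher in EEP (camera adjusted p = 1.09e-05, and adjusted p = 0.0932 with an estimated correlation). Krt5, Krt14 and Krt13 held most of their counts in EEP and so passed the low-count filter largely through that group. Their shared direction was thus partly set by the filter. Krt5, a keratin of basal cells, was at least 123-fold higher, with 616 counts in EEP and 0 in AS, and at least 81.3-fold higher without EEP 1. Krt15 and Krt14, also keratins of basal cells, had log2 fold changes of 4.07 (SE 1.18) and 3.84 (SE 1.51), and that of Krt14 was 3.18 without EEP 1. Most of their AS counts lay in AS 1, 52 for Krt15 and 7 for Krt14. Without AS 1 the pooled ratios were 300 for Krt15 (95% counting interval 82.8 to 2480) and 91.9 for Krt14 (16.3 to 3650). Krt5, Krt15 and Krt14 passed adjusted over the list alone, against 0 over all genes tested with edgeR, and DESeq2 gave them no adjusted p. Krt13, a keratin of the upper layers, had a value of 1.32 and did not pass. Its 36 AS counts all lay in AS 1, and without AS 1 it was at least 21.5-fold higher. The median of the list was 3.84 with Krt5 at its fitted value and at its lower bound. The list passed with each single EEP or AS library left out (adjusted p at most 0.00282) and with the mitochondrial share as a covariate (0.00417). The range over its alternatives was 1.22e-08 to 0.0932. Krt5 also stands in the mesothelium list, which had an adjusted p of 0.131.

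The smooth-muscle list was lower for 16 of 17 members in EEP (camera adjusted p = 2.64e-11, and adjusted p = 0.0548 with an estimated correlation). Adjusted over the list alone 9 members passed, against 0 over all genes tested with edgeR, whereas DESeq2 called 6 over all genes: Tpm2, Myl9, Tagln, Cnn1, Mylk and Des. The labels title the samples Endometrium and the design text says uterine tissues, and the amount of muscle layer per sample was not measured. Tpm2, the beta-tropomyosin of the contractile filament, stood at 254.5 ± 70.6 CPM against 1139 ± 538 CPM in AS, a log2 fold change of -2.16 (SE 0.422). Myl9, a myosin light chain, Tagln, the actin-binding transgelin, and Cnn1, calponin, had log2 fold changes of -1.79, -1.66 and -1.42, with Myl9 at -1.20 without AS 1 and -2.42 without EEP 1. Acta1, a striated-muscle actin from the skeletal muscle list, had one of -2.13 and was the 1 member of that list to pass adjusted over the list alone, against 0 over all genes tested with edgeR (list adjusted p = 0.323), and DESeq2 called it over all genes. AS 1 held the highest smooth-muscle values, 1760 CPM of Tpm2. The list passed without it and without every other single AS or EEP library (adjusted p at most 5.75e-08). The mitochondrial share was 18.9% to 76.3% in EEP and 68.7% to 75.2% in AS, and with the share as a covariate the adjusted p of the list was 3.04e-07 within a range of 2.69e-13 to 0.0548 over the alternatives.

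**Figure D3:**
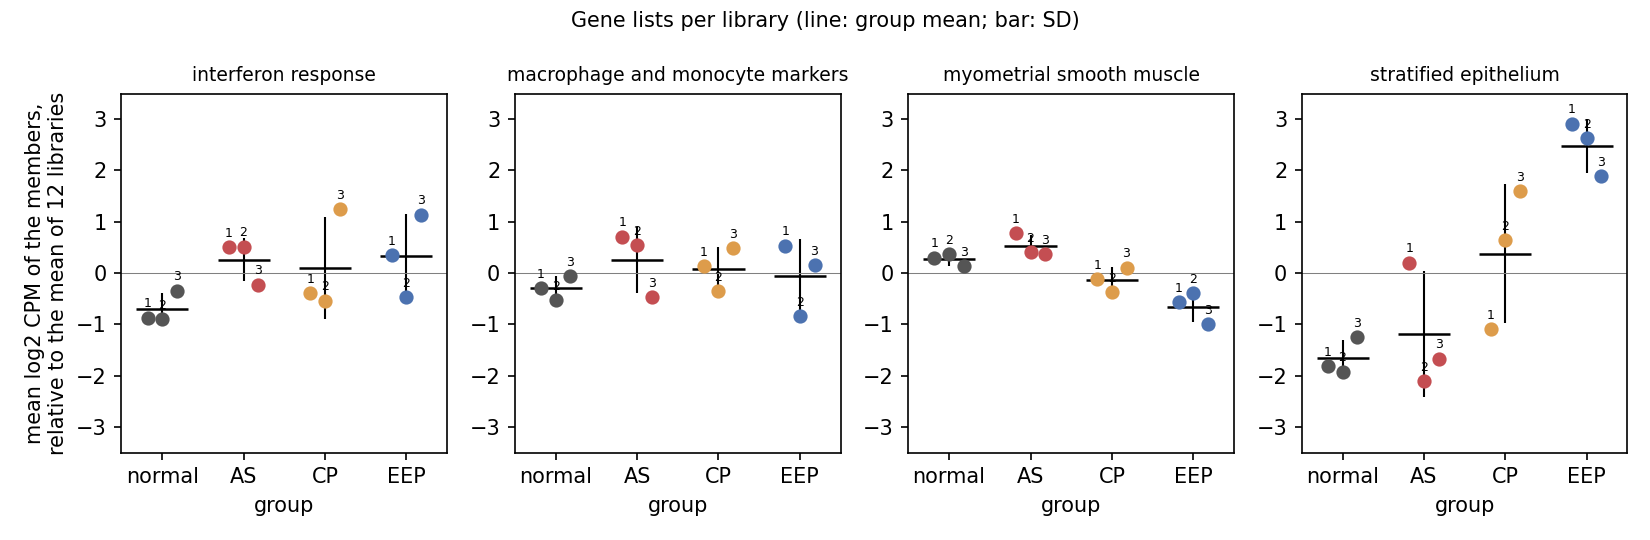
Mean log2 CPM of the measured members of 4 gene lists, relative to the mean of all 12 libraries (y axis), in each library by group (x axis); points are libraries with their replicate number, horizontal lines are group means and vertical bars the SD of 3 libraries. The stratified-epithelium list is highest and the smooth-muscle list lowest in EEP.

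Matrix genes were lower in EEP for 20 of 22 members (camera adjusted p = 0.00319, and adjusted p = 0.90 with an estimated correlation). Col5a1, a chain of a fibrillar collagen, had a log2 fold change of -0.95, Loxl2, a collagen-crosslinking enzyme, -0.74, and Bgn, the proteoglycan biglycan, -0.67, and none passed over all genes tested, with edgeR or DESeq2, or adjusted over the list alone. Without EEP 3 the list's adjusted p was 0.116 (range over alternatives 4.64e-06 to 0.90). Interferon (adjusted p = 0.786), macrophage (0.472), MHC class II (0.883), stromal (0.71), luminal epithelium (0.656), gland (0.515), Wnt (0.656), endothelium (0.718) and cell cycle lists (0.824) did not pass. RT1-Bb, a chain of a class II molecule, had a log2 fold change of 2.19 and passed adjusted over the list alone, as did Ckb, a brain-type creatine kinase induced by estrogen, at -1.53 (list adjusted p = 0.71), each 1 member against 0 over all genes tested with edgeR. DESeq2 called Ckb over all genes and gave no adjusted p for RT1-Bb. The TGF-beta and myofibroblast list had a median of 0.13, a mean of -0.16 and an adjusted p of 0.69.

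CP tissue was compared with AS tissue to see what the patch without cells changes. Fam111a was at 62.0 ± 24.2 CPM in CP against 2.27 ± 1.05 CPM in AS (SD, n = 3), a log2 fold change of 4.77 (SE 0.559, adjusted p = 0.00255 with edgeR's quasi-likelihood test). It was the single gene called, and higher in all 3 CP libraries than in all 3 AS libraries. Contractile genes of smooth muscle fell as a list with a median of -0.77 (adjusted p = 0.922 with an estimated correlation). The mean list score was -0.129 in CP, against 0.519 in AS and 0.264 in normal tissue. Marker genes of stratified epithelium had a median of 2.26 without passing.

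The smooth-muscle list was lower for 13 of 17 members in CP (camera adjusted p = 0.00183, and adjusted p = 0.922 with an estimated correlation). Tpm2 and Myl9 had log2 fold changes of -1.52 and -1.60. Mylk, the kinase that activates smooth-muscle myosin, stood at 402.4 ± 62.2 CPM against 928 ± 18.7 CPM, and Actg2, a smooth-muscle actin, had a log2 fold change of -2.27. The value of Actg2 rested on AS 1, at 2000 CPM against 374 and 324 CPM in AS 2 and AS 3, and was -0.86 without AS 1. These 4 were among the 5 that passed adjusted over the list alone, against 0 over all genes tested with edgeR, and DESeq2 called 3 of them over all genes, Tpm2, Myl9 and Mylk, and gave no adjusted p for Actg2. In the stratified-epithelium list (camera adjusted p = 0.127) 4 of 5 members were higher, and Krt5 was at least 28.9-fold higher, with 81 counts in CP and 0 in AS, and was the 1 member to pass adjusted over the list alone, against 0 over all genes tested with edgeR. DESeq2 called Krt5 over all genes, and also Spink5, a gene looked up here after its values were seen. The counts of Krt5 came from CP 2 and CP 3, at 8.9 and 5.33 CPM, with 0 in CP 1, the library with the highest mitochondrial share (82.5%). Krt5 was at least 39.1-fold higher without CP 1 and at least 16.4-fold without CP 2. Krt15 had a log2 fold change of 2.26, with 52 of its 54 AS counts in AS 1, and without AS 1 a pooled ratio of 81.1 (95% counting interval 22.2 to 674). RT1-Bb, as in EEP, had a log2 fold change of 2.07 and was the 1 class II gene to pass adjusted over the list alone, against 0 over all genes tested with edgeR and with DESeq2 (list adjusted p = 0.735). Collagen genes had a median of -0.37 (adjusted p = 0.127).

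At an unadjusted p under 0.05, 1667 genes separated CP from AS, against 695.4 by chance, and DESeq2 called 128. Without CP 2 the smooth-muscle list had an adjusted p of 0.174 (range over alternatives 7.15e-04 to 0.922), and the number of called genes was 5 without AS 1 and 3 without CP 1.

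EEP and CP tissue were compared with each other to see what the cells in the patch add. Marker genes of stratified epithelium were higher in EEP as a list, with a median log2 fold change of 1.81 and all 5 measured members higher (adjusted p = 0.522 with an estimated correlation). The smooth-muscle list was lower in EEP, with a median of -0.36 and 12 of 17 members lower (adjusted p = 0.522 with an estimated correlation). No single gene was called with edgeR's quasi-likelihood test. Spink5 stood at 36.5 ± 6.17 CPM in EEP and at 4.46 ± 4.35 CPM in CP (SD, n = 3), and had passed the low-count filter largely through EEP.

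The stratified-epithelium list had a camera adjusted p of 0.00346, and an adjusted p = 0.522 with an estimated correlation. Its members Krt5, Krt14 and Krt13 passed the low-count filter largely through EEP. Krt5 was at 18.5 ± 8.31 CPM against 4.74 ± 4.48 CPM, and Krt15 at 52.1 ± 12.7 CPM against 14.8 ± 9.03 CPM, with no overlap between the groups, which chance gives for 10% of genes. Krt5 had a log2 fold change of 1.95, and 2.77 without CP 2. Krt13 and Krt14 had log2 fold changes of 3.92 and 1.48. Without CP 3, which held 4 of 5 and 36 of 39 CP counts, their pooled ratios were 62.5 (95% counting interval 11.1 to 2480) and 29.6 (10 to 145), and without EEP 1 the log2 value of Krt14 was 0.82. The list passed with each single EEP or CP library left out (adjusted p at most 0.0497) and with the mitochondrial share as a covariate (0.0454). The range over its alternatives was 0.00158 to 0.522. The smooth-muscle list had a camera adjusted p of 0.00236, and an adjusted p = 0.522 with an estimated correlation. Des and Synm, an intermediate filament protein that binds desmin, had log2 fold changes of -1.11 and -1.29. No member of either list passed over all genes tested, with edgeR or DESeq2, or adjusted over the list alone.

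Of the other lists none passed: cell cycle (adjusted p = 0.138), Wnt (0.346), MHC class II (0.346), macrophage (0.812), collagen (0.522), stroma (0.61), luminal epithelium (0.812), gland (0.896) and TGF-beta (0.812). Within the last of these Tgfb3, a TGF-beta ligand, had 86 counts in EEP and 2 in CP, a pooled ratio of 24.2 (95% counting interval 6.49 to 203, and 19.3 without EEP 3), and was the 1 member to pass adjusted over the list alone, against 0 over all genes tested with edgeR and with DESeq2. With edgeR's quasi-likelihood test 0 genes were called between EEP and CP. DESeq2 also called 0, and 416 genes had an unadjusted p under 0.05, against 695.4 by chance. The 5 genes with the smallest p-values, all higher in EEP and none passing, were Fndc1, at least 14-fold higher with 0 counts in CP, Epb41l3, a membrane-skeleton protein (log2 fold change 2.57), Spink5 (3.01), Cnppd1 (3.07), and Mettl25, at least 15.5-fold higher with 0 counts in CP. Without CP 3 the values of Spink5 and Cnppd1 were 3.98 and 3.79. Fndc1, Epb41l3, Cnppd1 and Mettl25 had their lowest group mean in CP. Their normal means were 2.19, 15.5, 3.86 and 2.22 CPM and their AS means 3.7, 22.2, 6.27 and 1.42 CPM. The means were 0, 1.68, 0.632 and 0 CPM in CP and 4.03, 10.2, 5.59 and 2.64 CPM in EEP. Tgfb3 too was lowest in CP, at 0.14 CPM, against 3.01 in normal tissue, 2.05 in AS and 3.93 in EEP. These genes were thus low in CP more than high in EEP. Without CP 3 or EEP 3 the smooth-muscle list did not pass (adjusted p = 0.0529 and 0.0705, and 6.31e-05 to 0.522 over all alternatives). The mitochondrial share differed by -21.6 percentage points, EEP minus CP (exact permutation p = 0.3).

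Both patch groups were set against normal tissue to see how far they stood from the uninjured uterus. Spink5 was the 1 gene called between EEP and normal tissue, at 36.5 ± 6.17 CPM against 0.532 ± 0.234 CPM (SD, n = 3), a log2 fold change of 6.05 (SE 0.888, adjusted p = 0.0489 with edgeR's quasi-likelihood test). Here too Spink5 had passed the low-count filter largely through EEP. Without normal 1, normal 2, normal 3, EEP 2 or EEP 3 its adjusted p was 0.513, 0.0992, 0.129, 0.329 and 0.236 (range over all alternatives 4.61e-12 to 0.513), although its log2 fold change stayed between 5.77 and 6.40. At an unadjusted p under 0.05 there were 1051 genes, DESeq2 called 75, and without EEP 1, the library nearest to the normal ones, 200 genes were called, Spink5 among them. Between CP and normal tissue edgeR called 0 genes, the smallest adjusted p being 0.0708, whereas 1760 genes had an unadjusted p under 0.05 and DESeq2 called 274. The same edgeR test called 585 genes with the 2 groups fitted alone and 11 with the replicate number as a block. Without normal 2 there were 4 called genes for EEP and 6 for CP.

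The last question was whether the patches moved injury-changed genes back. Fam111a, the 1 gene called after injury with edgeR, was called in the opposite direction in both EEP and CP against AS. DESeq2 called 32 genes after injury, and those it called back were not counted for either patch. For EEP they included Igfbp3 (log2 fold changes -3.22 in AS vs normal and 2.316 in EEP vs AS) and Abhd12 (1.535 and -1.693). For 1 injury gene, independent lists give an expectation of 1.44e-04 such genes for EEP and 7.19e-05 for CP. The AS libraries are shared by both comparisons, so this expectation does not hold for a gene low in AS alone. In 20 simulations the patch libraries were drawn at the observed AS level, so their mean of 0 was close to fixed in advance. Neither value separates a return under the patches from a low level particular to the AS libraries. A correlation of the injury change with the EEP-minus-CP difference needs more than 1 called gene and could not be computed as fixed. Across the 772 genes at an unadjusted p under 0.05 after injury, a set chosen after the data were seen, Spearman's rho was -0.273 and 67% of genes had opposite signs; genes are not independent replicates. Without EEP 1 rho was 6.32e-04.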

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

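Removal of the mitochondrial genes, the mitochondrial share as a covariate, leaving out EEP 1 and AS 1 together, and the set of genes at an unadjusted p under 0.05 for the relation between injury and patch were chosen only after the results were seen. Counts are given in the order AS vs normal, EEP vs AS, CP vs AS, EEP vs CP, EEP vs normal and CP vs normal, where edgeR called 1, 2, 1, 0, 1 and 0 genes. RLE scaling and an added 2-fold threshold gave the same counts. DESeq2 called 32, 140, 128, 0, 75 and 274, and all but 4 of these (in CP vs AS, 124 of 128) had an unadjusted p under 0.05 in edgeR. Without a low-count filter the counts were 154, 143, 230, 5, 232 and 445, and at an unadjusted p under 0.05 with a 2-fold change 670, 1183, 1421, 343, 861 and 1535. The stricter filter gave 0 for EEP vs normal. The 2 groups fitted alone gave 1 for EEP vs AS, 3 for EEP vs normal and 585 for CP vs normal, and the replicate block gave 3 for EEP vs AS, 4 for EEP vs normal and 11 for CP vs normal. The share as a covariate gave 2 for CP vs AS and 2 for EEP vs normal, and removal of the mitochondrial genes gave 0 for EEP vs normal. Leaving out EEP 1 and AS 1 together gave 27, 87, 37, 0, 854 and 738. Single replicates left out gave 1 to 6 for AS vs normal, with 6 without normal 2 and 2 without AS 1. They gave 1 to 19 for EEP vs AS, with 1 without AS 2, 3 without AS 1 and 19 without EEP 1, and 1 to 5 for CP vs AS, with 5 without AS 1 and 3 without CP 1. For EEP vs normal they gave 0 to 200, with 4 without normal 2, 200 without EEP 1 and 0 without each other library, and for CP vs normal 0 to 6, with 6 without normal 2. For EEP vs CP they gave 0. Of the lists 7, 3, 1 and 2 passed in the first 4 comparisons, and 0, 0, 0 and 0 with an estimated correlation. With the share as a covariate 11, 6, 1 and 7 passed, and without EEP 1 and AS 1 together 5, 5, 6 and 7. Removal of the mitochondrial genes gave 6 lists for AS vs normal. Single replicates left out gave 4 to 9 (4 without normal 2), 3 to 5 (5 without AS 1 or AS 3), 0 to 6 (6 without AS 1, 2 without CP 1 or CP 3, 0 without CP 2) and 2 to 6 lists (4 without CP 3 or EEP 2, 6 without EEP 1). In the edgeR fits counted, 1 to 2 genes called after injury were called in the opposite direction in EEP and in CP against AS. The number was 2 without AS 1 and 2 without EEP 1 and AS 1 together. DESeq2 was not part of this count. The rho of the injury change with the EEP-minus-CP difference ran from -0.304 to 6.32e-04 with single replicates left out, turned to 6.32e-04 without EEP 1 and to 0.241 without EEP 1 and AS 1 together, and was -0.60 with the share as a covariate. Mmp7 in AS vs normal ran from -0.10 to 3.15 with single replicates left out, turned to -0.10 without AS 1, where most of its counts lay, and to -0.0841 without EEP 1 and AS 1 together. Of the values of named genes under the alternatives 971 kept their direction and their side of the threshold, 48 came to pass it, 10 no longer passed it and 2 turned. Of the values of passing lists 122 stayed past the threshold and 34 did not, 13 of these with the estimated correlation. A low count after leaving out a library follows in part from fewer samples; for the other changes the cause was not tested. Depth limits what can be seen: 3 counts stand for up to 0.867 CPM, so the gene levels reported as 0 are levels not detectable at this depth.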

Other observations

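The tests of the mitochondrial share, of markers of other tissue, of the genes near Fam111a, of a strain difference and of a wrong label, the relations between library scores and the look at the authors' q-values were chosen only after the results were seen. The tests by thinning of counts and by other splits were chosen before.

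EEP and AS tissue differed in genes of 2 tissue layers, markers of stratified epithelium and contractile genes of smooth muscle, with the preset correlation and not with an estimated correlation (adjusted p = 0.0932 and 0.0548). Across the 12 libraries the estrogen-induced score followed the luminal epithelium score (Pearson r = 0.788, permutation p = 0.00264, adjusted p = 0.00792 over 3 relations). Spearman's rho was 0.846, and r was 0.777 without EEP 3 and normal 2. The mitochondrial share and the smooth-muscle score had r = 0.156 (permutation p = 0.63), and -0.191 without EEP 1 and normal 3. These are scores of whole tissue, and the share of each layer in a sample was not measured.

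Markers of stratified epithelium and Spink5 were higher in EEP than in AS. A difference in depth is argued against, because the highest adjusted p of the list was 3.57e-05 over 5 thinnings of every library to 1202525 nuclear counts. RNA quality that follows the mitochondrial share is argued against as the whole cause, since with the share as a covariate the adjusted p was 0.00417 and the median went from 3.84 to 3.08. Both values use the preset correlation, and with an estimated correlation the list did not pass in the full data (adjusted p = 0.0932). Stratified tissue of the cervix or vagina in the samples stays open: of the 10 listed markers with over 3 counts, 9 were higher in EEP, and growth of such cells inside the horn would give the same. An effect of the patch and its cells is named by the design and also stays open as untested against that.

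Fam111a was low in the AS libraries alone, at 1.17, 3.26 and 2.37 CPM. A difference in depth is argued against, as its highest adjusted p over the thinnings was 0.00401. Loss of a wider region around the gene is argued against: the 7 tested genes that start within 1 Mb had log2 fold changes from -0.82 to 1.07, with a median of -0.428. A strain difference of the AS animals stays open, because 1 gene was over 3-fold lower in every AS library than in each other library and CP also had 1 such gene (Epb41l3), too few to decide. A loss of the gene alone was not tested, and an effect of the injury that both patches lift stays open as untested.

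EEP 1 was closer to the normal libraries than EEP 2 and EEP 3. A difference in depth is argued against, since after thinning its correlation with normal libraries was 0.864 against 0.794 and 0.742, a mean gap of 0.07. The SD of that gap over the 5 thinnings was 6.47e-04, which covers the drawing of counts and not the spread between samples. A normal sample under the EEP 1 label stays open. Of 30 genes over 5-fold above the highest normal library in EEP 2 and EEP 3, 5 were so in EEP 1 (Gp6, Krt15, Krt5, Lgals7 and Spink5, chosen after their values were seen) and 17 were not above that library. Krt5, Krt15 and Spink5 summed to 122 CPM in EEP 1 and to at most 3.84 CPM in normal libraries, but they were singled out with EEP 1 among the libraries, and stratified tissue in a sample would raise them too. RNA quality that follows the mitochondrial share stays open, with r = -0.398 between share and correlation with normal over the other 8 injured libraries (permutation p = 0.336, and r = -0.251 without EEP 2 and CP 1). The unpatched AS 2 and AS 3 stood at 0.864 and 0.858 before thinning, against 0.883 for EEP 1 and 0.823 and 0.752 for EEP 2 and EEP 3. An effect of the patch on the distance to normal tissue stays open as untested.

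With 3 libraries against 3 there are 10 splits, the real one included, too few for a share under 0.05. As many genes as in the real split were called in 2 of 10 splits for AS vs normal (real 1, highest other 8), 2 for EEP vs AS (2, highest other 2), 1 for CP vs AS (1, highest other 0) and 2 for EEP vs normal (1, highest other 6). For EEP vs CP and CP vs normal all 10 splits gave 0 genes with edgeR, where 416 and 1760 genes had an unadjusted p under 0.05 in the real split and DESeq2 called 0 and 274. As many lists passed in 3 splits for AS vs normal (7, highest other 11), 8 for EEP vs AS (3, highest other 8), 9 for CP vs AS (1, highest other 9) and 7 for EEP vs CP (2, highest other 6). The correlation of the injury change with the EEP-minus-CP difference was as far from 0 in 4 splits (real -0.273, highest other size 0.414). The splits with 8 and 6 genes set normal 2 with AS 2 and AS 3 and with EEP 2 and EEP 3. Such splits point to a structure of the samples. Luminal epithelium scores were -0.848 in normal 2 and -1.73 and -0.642 in AS 2 and AS 3. They were -0.312 and -1.08 in EEP 2 and EEP 3. The scores of normal 1, normal 3, AS 1 and EEP 1 were 0.259, 0.639, 1.62 and 1.77. Both splits thus set libraries with lower scores against libraries with higher ones. The score was looked up after the splits were seen, and whether epithelium lies behind them was not tested. The list counts of the splits all use the preset correlation.

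The authors' q-values were under 0.05 for 7 genes in AS vs normal and for 1 in CP vs normal, Hnf4g, and for 0 in the other 4 comparisons. In each of the 7 the 3 normal libraries held identical counts, 1 each or 2 each. The AS libraries held 0 counts, except for LOC120095489 with 5, 4 and 4. Their totals over the 12 libraries were 8 to 84 counts, and LOC102554173 alone was tested here (adjusted p = 0.937).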
